A study of Mus musculus with 6 samples.

How the data were processed

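Brain endothelial cells had been sorted on CD31 (PECAM1) from mouse embryos at embryonic day 11.5, and the mothers had received tamoxifen at embryonic day 9.5, per the labels' protocols. The strain was given as C57BL/6 x 129/Sv, and the genetic modification as a tamoxifen-inducible Cre line together with an Axin1 allele at the R26 locus. Polyadenylated RNA was purified with a small-scale column kit and made into cDNA with the SMARTer ultra-low-input kit, per the labels' protocols. The 6 libraries were assigned from their descriptions to 2 groups, 3 with wildtype Axin1 (control) and 3 overexpressing Axin1. The descriptions call the libraries of a group biological replicates. They do not state litters, pools or sex, so each p-value measures the spread between these libraries only.

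The authors deposited 1 table per library, with a read count and an RPKM/FPKM value for each of 22958 RefSeq gene entries, per the file headers. The submitters' processing notes name Bowtie and the mm9 build without versions. The counting program, the strand setting and the treatment of reads with several matches are not given in the sources used here. The counts were whole numbers in every library and were used as deposited. The RPKM values deposited by the authors were used only as a check: the ratio of reads to RPKM differed between libraries by 1 common factor, within 1%, for at least 82.2% of entries. The log2 fold changes from group means of RPKM (pseudocount 1) had a Pearson r of 0.923 across genes with those of the count model, and genes are not independent replicates. Gene symbols repeated over several entries (794 entries) held 0.0753% to 0.0867% of the reads of a library, 170 entries joined several symbols, and 5154 entries had no read in any library. The reference annotation available here is of another build than mm9, so no coordinates are given.

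Library totals ranged from 10772492 to 14234409 reads. Genes were kept with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 12661 genes. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit) on the counts, with TMM normalisation, no covariates and Benjamini-Hochberg adjustment over all tested genes, at an adjusted p of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic, and intervals are 95% confidence intervals. Levels are TMM-normalised CPM, given as mean ± SD over the 3 libraries of a group. Normalisation factors lay between 0.975 and 1.02, and the common biological coefficient of variation was 25.3%. No pair of libraries agreed within counting noise: chi-square per degree of freedom over genes ranged from 16.4 to 61.5.

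Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 21 lists. The tests were repeated with an estimated correlation and with the directional test of fry. With an estimated correlation several lists often share 1 adjusted p, since the adjustment ties them. The lists held Wnt/beta-catenin target genes, Wnt pathway receptors and transducers, blood-brain barrier genes, fenestrated or leaky vessel genes, Notch pathway genes, TGF-beta and BMP pathway genes, ADAMTS-like and microfibril genes, basement membrane genes, VEGF and tip cell genes, arterial genes, venous genes, pan-endothelial markers, proliferation genes, p53 and apoptosis genes, hypoxia and glycolysis genes, dissociation stress genes, and markers of neural cells, pericytes and mesenchyme, macrophages and microglia, erythroid cells, and megakaryocytes and platelets. Sex-linked marker genes were the remaining list and are given as values per library only. Of the 414 list entries, 6 were found under an older symbol and 1 was not found.

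The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were Axin1, Axin2, Adamtsl2, Lef1, Slc2a1, Plvap and Cldn5 in any case. Further named genes were the 10 with the largest fold change in each direction among genes past the threshold with non-overlapping groups and a mean of at least 5 CPM, predicted genes and pseudogenes left out. Up to 4 members of each list with the smallest p, and markers used in a technical test, completed the rule, and the text prints part of these. Genes named outside the rule are said to be so. Counts of genes with near-identical copies or processed pseudogenes (Pfn1 and ribosomal protein genes among those named) are uncertain. So are those of Fn1, Abcc9, Plek, Tagln and Slc7a7, whose exons overlap a gene on the opposite strand in the reference annotation.

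The model was tested on simulated counts for the same 12661 genes, with 200 genes changed by 1.5-fold to 8-fold. A list of 26 further genes was lowered by 1 on the log2 scale. Counts were drawn independently for each gene, so correlation between genes was not simulated. Of 50 genes at each fold size the model called 4% at 1.5-fold, 30% at 2-fold, 80% at 4-fold and 92% at 8-fold. It made 122 calls, 8 of them on unchanged genes, and 3 calls where nothing was changed. Alternatives were the DESeq2 Wald test (DESeq2 1.42.0), DESeq2 size factors or upper-quartile scaling within edgeR, no filter, a filter at 5 CPM in 3 libraries, leaving out each library, the replicate number as a block, the number in the library title as a block, voom with that number as a random block, voom with sample quality weights, 1 surrogate variable (sva 3.50.0), and erythroid genes left out of the totals. A correction of each library for its trend with GC content and transcript length, list tests without the members called on their own, and the estimated correlation within each alternative, were added after seeing the data. Both voom alternatives tested the lists on the same voom log2 values without the block or the weights, so their list results are identical. The title number as a fixed block used only the 4 libraries that share numbers and left almost no residual degrees of freedom. The small p values and the number of calls of that fit therefore rest on little. Alternatives planned for normalised values were not run because counts were at hand. The tests of the p53 and apoptosis list with covariates replaced earlier ones within 1 library and by rank correlation over 3 libraries, which rested on too few samples and had led to the same readings. A comparison of ribosomal protein genes with all genes under other scalings, whose outcome no scaling can change, and tests of solute carrier and ribosomal protein genes as sets, both picked from the same data, were left out.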

Results

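Expression was measured by RNA sequencing in CD31-sorted endothelial cells of the embryonic mouse brain. There were 3 control libraries with wildtype Axin1 and 3 libraries overexpressing Axin1, a scaffold of the complex that marks beta-catenin for degradation. Control libraries 1, 2 and 3 held 11728908, 13035808 and 10772492 reads assigned to genes, and Axin1 libraries 1, 2 and 3 held 12578046, 14234409 and 11633853. The series asked how brain endothelial expression changes when Axin1 is overexpressed, and its title names ADAMTSL2 in Wnt/beta-catenin-regulated vascular development of the central nervous system.

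Axin1 (NM_009733 among its RefSeq identifiers) rose from 21.1 ± 3.74 CPM in the controls to 69.4 ± 9.24 CPM in the Axin1 libraries (SD, n = 3 each), a 3.29-fold change. Adamtsl2 (NM_029981), which encodes a secreted ADAMTS-like glycoprotein of the extracellular matrix, fell from 355 ± 41.9 to 174 ± 6.85 CPM, 2.03-fold. Slc2a1, the glucose transporter of the blood-brain barrier, fell from 3673 ± 186 to 1489 ± 169 CPM. Apcdd1, a membrane-bound Wnt inhibitor and Wnt target, fell from 112 ± 23.5 to 15.9 ± 3.90 CPM. For each of these 4 genes the groups did not overlap.

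The log2 fold change of Axin1 was 1.72 (SE 0.17) with an edgeR adjusted p of 0.0103. The deposited counts do not separate transgene from endogenous reads. For Adamtsl2 it was -1.02 (SE 0.12, 95% confidence interval -1.29 to -0.76) with an edgeR adjusted p of 0.0181. Without control 2 the edgeR adjusted p was 0.0915 for Axin1 and 0.132 for Adamtsl2, and without Axin1 library 2 it was 0.0721 and 0.146. Without Axin1 library 3 it was 0.0545 for Adamtsl2. The fold changes in the 6 fits that left out 1 library stayed between 1.60 and 1.85 for Axin1 and between -1.11 and -0.95 for Adamtsl2.

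Over all 12661 tested genes, 107 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 45 higher and 62 lower in the Axin1 libraries. More than 2-fold changes were seen in 57 of them, 24 higher and 33 lower. Groups did not overlap for any of the 107, while 3008 of all tested genes (23.8%) had non-overlapping groups. Chance gives 10% on average over splits of the libraries, and the share was not computed for the other splits. DESeq2 called 672 genes, 376 higher and 296 lower, among them 106 of the 107. The number of calls depended on single libraries: it was 10 without control 1, 695 without control 3, 33 without Axin1 library 1 and 18 without Axin1 library 3. Without control 2 or without Axin1 library 2, edgeR's test called 0 genes, with 1539 and 1733 genes at an unadjusted p under 0.05 against 2177 with all libraries. All 107 genes kept their direction in each of these 6 fits. Their non-overlapping groups made this outcome nearly certain beforehand, so it is no sign of stability.

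**Figure D1:**
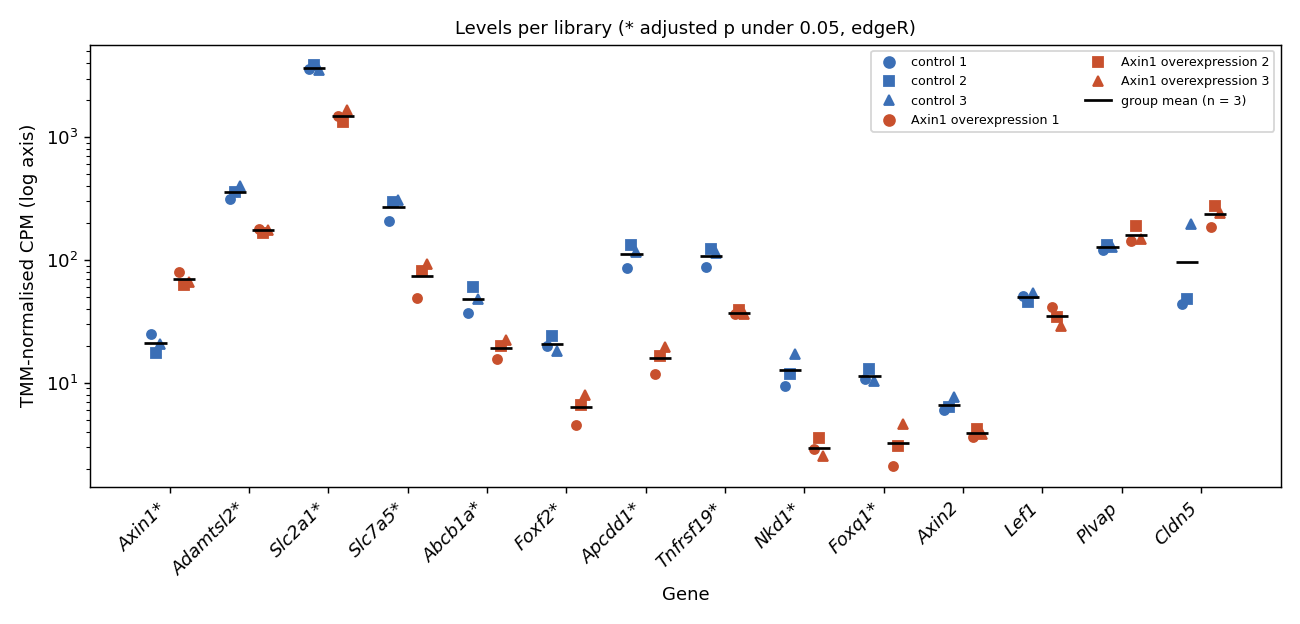
TMM-normalised CPM of 14 genes in the 6 libraries on a log axis, with control libraries in blue, Axin1 libraries in orange-red, a bar at the mean of each group (n = 3), and an asterisk where edgeR's adjusted p was under 0.05. Cldn5 in control 3 (196 CPM) lies with the Axin1 libraries (186 to 275 CPM) and apart from controls 1 and 2 (44.0 and 48.2 CPM).

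Among genes that fell, the largest fold changes after Apcdd1 (log2 -2.82, SE 0.23) were those of Ptgfrn, an immunoglobulin-domain membrane protein, at -2.42, and of Stra6, the receptor for retinol-binding protein, at -2.35. Stra6 went from 45.2 ± 8.03 to 8.88 ± 1.27 CPM. The Dishevelled-binding Wnt antagonist Nkd1 and Fam13a each fell by 2.09 on the log2 scale. The amino acid transporters Slc7a5 and Slc38a3 each fell by 1.86, from 270 ± 53.4 to 74.5 ± 22.4 CPM and from 227 ± 44.5 to 62.8 ± 22.6 CPM. The transcription factors Foxq1, Tshz2 and Foxf2 fell by 1.81, 1.76 and 1.71. Adjusted p in edgeR ranged from 0.00461 for Apcdd1 and Stra6 to 0.0492 for Foxq1. For these 10 genes the edgeR adjusted p was 0.052 to 0.213 without control 2 and 0.0721 to 0.175 without Axin1 library 2. It was over 0.05 for 7 of them without control 1 (up to 0.158), for 5 without Axin1 library 1 (up to 0.079) and for 7 without Axin1 library 3 (up to 0.0869).

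Among genes that rose, the actin-binding protein gene Pfn1 had the largest fold change, from 213 ± 65.4 to 835 ± 252 CPM (log2 1.97, SE 0.29), a count made uncertain by processed pseudogenes. Ptchd1, which encodes a patched-domain membrane protein, went from 8.87 ± 0.32 to 34.0 ± 6.34 CPM (log2 1.94). Rheb, the small GTPase that activates mTORC1, rose by 1.82 on the log2 scale, and mitochondrial isocitrate dehydrogenase Idh2 by 1.73. The thrombin receptor gene F2r went from 160 ± 59.6 to 523 ± 60.0 CPM (log2 1.71). Zcrb1, Npdc1, the p38 pathway kinase gene Map2k3 and the dUTPase gene Dut rose by 1.70, 1.58, 1.58 and 1.54. Adjusted p in edgeR ranged from 0.00976 for Ptchd1 to 0.0492 for Npdc1. For these 9 genes the edgeR adjusted p was 0.0543 to 0.185 without control 1, 0.0915 to 0.214 without control 2 and 0.0788 to 0.158 without Axin1 library 2. Without Axin1 library 1 it was over 0.05 for Pfn1, F2r and Dut (up to 0.0869), and without Axin1 library 3 for 7 of the 9 (up to 0.126).

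Of 22 measured Wnt/beta-catenin target genes, 4 fell and 0 rose. These were Apcdd1, Tnfrsf19, a TNF receptor family member (log2 -1.54), Nkd1 and Foxq1. Adjusted over the list alone, 6 fell, with Lef1 and Tcf7, the DNA-binding partners of beta-catenin, added. Lef1 went from 49.9 ± 4.47 to 34.8 ± 6.33 CPM (log2 -0.52, edgeR adjusted p over all genes 0.167). Tcf7, singled out after its values were seen, had a log2 fold change of -1.57 (edgeR adjusted p 0.0523). Axin2, a feedback target of the pathway, went from 6.62 ± 0.89 to 3.87 ± 0.31 CPM (log2 -0.77, 95% confidence interval -1.39 to -0.16, edgeR adjusted p 0.198). The list lay lower in the Axin1 libraries by camera (adjusted p 0.00667, median log2 -0.28), with an adjusted p = 0.699 with an estimated correlation (unadjusted 0.0483). By fry its adjusted p was 0.0472. Leaving out the 4 called members, which weakens the list by construction, gave a camera adjusted p of 0.464. In the 4 libraries that share title numbers, with that number as a block, it was 0.0532. Over the alternatives tried singly it ranged from 4.8e-04 to 0.699. For Tnfrsf19 the edgeR adjusted p was 0.0795 without control 2 and 0.0788 without Axin1 library 2.

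Of 26 measured blood-brain barrier genes, 5 fell and 0 rose. Besides Slc2a1 (log2 -1.30, SE 0.11, edgeR adjusted p 0.00461) and Slc7a5, these were Foxf2, the drug efflux pump gene Abcb1a at -1.32 and the thiamine transporter gene Slc19a3 at -1.37. Slc19a3 lay outside the rule for named genes. Adjusted over the list alone, 15 fell. Among these, singled out after their values were seen, were the lipid transporter gene Mfsd2a (log2 -2.13), the thyroid hormone transporter gene Slco1c1 (-2.63), the tight junction gene Ocln (-1.95) and the transferrin receptor gene Tfrc (-1.34), whose edgeR adjusted p values over all genes were 0.222, 0.0981, 0.0873 and 0.106. The list lay lower by camera (adjusted p 1.11e-06, median log2 -1.03), with an adjusted p = 0.699 with an estimated correlation (unadjusted 0.0666) and 0.0724 by fry. Without its 5 called members the camera adjusted p was 0.00547, with an adjusted p = 0.745 with an estimated correlation. For Slc2a1 the edgeR adjusted p was 0.052 without control 2 and 0.0721 without Axin1 library 2, and Abcb1a had 0.0782, 0.198, 0.0778, 0.156 and 0.0781 without control 1, control 2 and Axin1 libraries 1, 2 and 3.

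Cldn5, the main claudin of brain endothelium, was among the 5 barrier genes with a positive log2 fold change, none of which passed edgeR's test. It was at 95.9 ± 86.4 CPM in the controls and 234 ± 44.9 CPM in the Axin1 libraries (log2 1.29, 95% confidence interval -0.36 to 2.94, edgeR adjusted p 0.395). The controls read 44.0, 48.2 and 196 CPM. Without control 3 the log2 fold change was 2.33 with an edgeR adjusted p of 6.8e-04. In the 4 libraries that share title numbers it was 2.30 with an edgeR adjusted p of 3.6e-08. Both fits leave out control 3, the control with the high Cldn5 level, so neither small p is separate support for a rise.

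**Figure D2:**
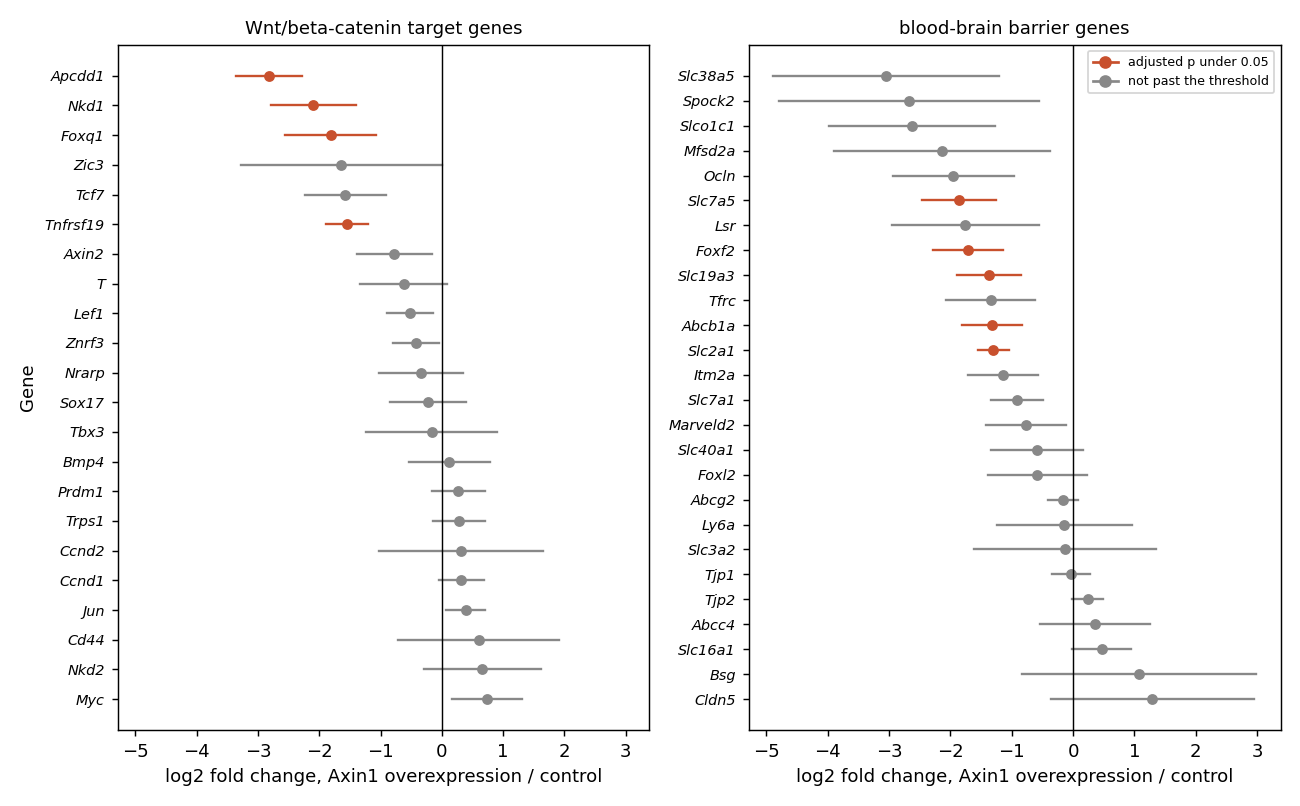
Log2 fold change of each measured Wnt/beta-catenin target gene (left) and blood-brain barrier gene (right), Axin1 overexpression over control (n = 3 each), with bars for the 95% confidence interval and genes past edgeR's adjusted p of 0.05 in orange-red. Apcdd1 at -2.82 and Slc38a5, outside the rule for named genes, at -3.05 have the lowest values of the panels, and Slc38a5 has the wider interval.

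Of 12 fenestrated or leaky vessel genes, Esm1, an endothelial proteoglycan gene, rose (log2 0.89, edgeR adjusted p 0.0421). The list had 2 genes higher and 1 lower when adjusted over the list alone (camera adjusted p 0.37). For Esm1 the edgeR adjusted p was 0.116, 0.198, 0.077, 0.152 and 0.0632 without control 1, control 2 and Axin1 libraries 1, 2 and 3. Plvap, which forms the diaphragms of fenestrae, went from 127 ± 6.69 to 159 ± 24.5 CPM (log2 0.33, 95% confidence interval 0.03 to 0.62, edgeR adjusted p 0.253). None of 31 Wnt receptors and transducers changed by edgeR over all genes, and adjusted over the list alone 1 rose, the transcription factor gene Tcf7l2 (log2 0.57, edgeR adjusted p over all genes 0.0552, list camera adjusted p 0.672). Tcf7l2 passed in 8 of 18 alternatives, with an adjusted p between 0.00376 (DESeq2) and 0.21, and the receptor gene Fzd6 (log2 -0.71, edgeR adjusted p 0.191) in 1, at 9.6e-04 in the 4 libraries that share title numbers. Of 16 ADAMTS-like and microfibril genes Adamtsl2 fell and 0 rose, and adjusted over the list alone 1 fell and 1 rose. The second was the protease gene Adamts1 (log2 1.18, edgeR adjusted p over all genes 0.0798), which passed in 4 of 18 alternatives (DESeq2 adjusted p 8.1e-05). The list had a camera adjusted p of 0.37.

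Of 20 basement membrane genes 3 fell, which were Agrn (agrin, log2 -0.73), Fn1 (fibronectin, -0.70) and Sparc (a collagen-binding matrix protein, -0.47), at edgeR adjusted p values of 0.038, 0.0438 and 0.0492. Adjusted over the list alone 3 fell and 3 rose (camera adjusted p 0.794). Sparc went from 4976 ± 73.5 to 3601 ± 134 CPM. Of 16 Notch pathway genes the ligand gene Jag1 fell (log2 -0.74, edgeR adjusted p 0.0452), and adjusted over the list alone 1 fell and 1 rose (camera adjusted p 0.799). Of 14 arterial genes Jag1 alone changed, and adjusted over the list alone 2 fell and 1 rose (camera adjusted p 0.886). The median of the arterial list was 0.10 and its mean -0.003 on the log2 scale. Of 19 VEGF and tip cell genes Igfbp3, an IGF-binding protein gene, rose (log2 0.70, edgeR adjusted p 0.0438), and adjusted over the list alone 2 rose (camera adjusted p 0.338). By edgeR over all genes, none of 10 venous genes or 26 TGF-beta and BMP pathway genes changed. Adjusted over the list alone 1 venous gene rose and 1 fell (camera adjusted p 0.794), and 0 TGF-beta and BMP genes changed (camera adjusted p 0.746). Some named members of these lists passed only in alternatives. Of 18 alternatives, Col15a1 (log2 0.63) passed in 7, Flt4 (0.62) and Hey1 (0.88) in 6 each and Gja4 (-0.98) in 4. Aplnr (-0.39) passed in 3, and Robo4 (0.29) and Tgfb2 (-0.50) in 1 each. For Agrn, Fn1, Sparc, Jag1 and Igfbp3 the edgeR adjusted p lay over 0.05 without control 1 (0.104 to 0.159), control 2 (0.198 to 0.21), Axin1 library 1 (0.077 to 0.113), Axin1 library 2 (0.152 to 0.169) or Axin1 library 3 (0.0546 to 0.128).

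All 14 measured p53 and apoptosis genes had positive log2 fold changes, with a median of 0.69, and 0 of them passed edgeR's test over all genes. Adjusted over the list alone 1 rose, the p53 antagonist gene Mdm2, from 68.6 ± 17.9 to 150 ± 26.7 CPM (log2 1.13, edgeR adjusted p over all genes 0.0635). The death receptor gene Eda2r had a log2 fold change of 1.31 and Bax one of 0.73 (edgeR adjusted p 0.187 and 0.201). By camera the list lay higher in the Axin1 libraries (adjusted p 4.6e-04), with an adjusted p = 0.745 with an estimated correlation and 0.165 by fry. Of 18 dissociation stress genes 0 passed edgeR's test over all genes, and adjusted over the list alone 2 rose, the chaperone gene Hspa1a (log2 1.75) and the immediate early gene Junb (log2 1.78), at edgeR adjusted p values over all genes of 0.0561 and 0.0959. That list lay higher by camera (adjusted p 0.00667, median log2 0.42), with an adjusted p = 0.745 with an estimated correlation and 0.398 by fry. Without control 3 its camera adjusted p was 0.369, without Axin1 library 3 it was 0.0613, and in the 4 libraries that share title numbers it was 0.584. DESeq2 called Mdm2, Eda2r, Bax, Hspa1a and Junb at adjusted p values of 8.1e-05, 0.00446, 0.0378, 1.6e-05 and 9.3e-04. Macrophage and microglia markers stood at a mean log2 CPM of 4.54, 6.54 and 7.66 in Axin1 libraries 1, 2 and 3 and at 5.51, 6.13 and 5.14 in controls 1, 2 and 3.

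Of 20 proliferation genes the replication helicase gene Mcm6 rose from 138 ± 42.6 to 336 ± 40.2 CPM (log2 1.28, edgeR adjusted p 0.0491) and 0 fell, with the same count adjusted over the list alone. The list's median was -0.10 (camera adjusted p 0.464), and without Axin1 library 1 the camera adjusted p was 0.021, lower in the Axin1 libraries, with an adjusted p = 0.776 with an estimated correlation. For Mcm6 the edgeR adjusted p was 0.154, 0.21, 0.0681, 0.159 and 0.131 without control 1, control 2 and Axin1 libraries 1, 2 and 3. Of 15 hypoxia and glycolysis genes Slc2a1 alone changed, and adjusted over the list alone 1 fell and 2 rose (camera adjusted p 0.794). The median of that list was -0.08 and its mean 0.02.

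None of 20 pan-endothelial markers changed by edgeR, over all genes or adjusted over the list alone (camera adjusted p 0.886, direction down, median -0.02, mean 0.01). Pecam1, which encodes the CD31 used for sorting, lay between 1182 and 1455 CPM in all libraries. Cdh5, the endothelial cadherin gene, went from 593 ± 221 to 950 ± 28.8 CPM (log2 0.68, edgeR adjusted p 0.218), with 432, 502 and 846 CPM in controls 1, 2 and 3. Without control 3 its log2 fold change was 1.01 with an edgeR adjusted p of 0.00222, and DESeq2 gave an adjusted p of 0.0426 with all libraries.

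Markers of other cells varied between libraries of both groups. None of 15 macrophage and microglia markers passed edgeR's test, over all genes or adjusted over the list alone (camera adjusted p 0.338, median log2 1.13). The macrophage gene C1qb lay at 94.9, 156 and 83.4 CPM in controls 1, 2 and 3 and at 46.7, 271 and 496 CPM in Axin1 libraries 1, 2 and 3. Of 10 erythroid markers the carbonic anhydrase gene Car2 fell (1209 ± 164 to 455 ± 86.0 CPM, log2 -1.41, edgeR adjusted p 0.0208), also adjusted over the list alone (camera adjusted p 0.282). Without control 1, control 2 or Axin1 library 2 the edgeR adjusted p of Car2 was 0.0624, 0.132 or 0.0968. The embryonic globin gene Hbb-y ranged from 134 CPM in Axin1 library 1 to 1887 CPM in Axin1 library 3 and from 439 to 1835 CPM in the controls. None of 13 megakaryocyte and platelet markers changed over all genes. Clec1b alone fell when adjusted over the list alone (log2 -0.60, edgeR adjusted p over all genes 0.0681), and over all genes it passed in 6 of 18 alternatives (DESeq2 adjusted p 0.00443). That list's median was 0.37 and its mean 0.32, while camera gave the direction down at an adjusted p of 0.948. Without Axin1 library 1 the camera adjusted p was 1.6e-07 for macrophage markers, 1.2e-04 for megakaryocyte markers and 0.0417 for pericyte and mesenchyme markers, all higher, and each had an adjusted p = 0.776 with an estimated correlation. Without Axin1 library 3 it was 0.0038 for erythroid markers, lower, with an adjusted p = 0.796 with an estimated correlation. Erythroid markers were also lower in the 4 libraries that share title numbers (camera adjusted p 0.00142) and with 1 surrogate variable (0.00403), with an adjusted p = 0.808 and an adjusted p = 0.679 with an estimated correlation.

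By edgeR, 0 of 16 pericyte and mesenchyme markers and 0 of 15 neural markers changed over all genes or adjusted over the list alone (camera adjusted p 0.464 and 0.746). In the 4 libraries that share title numbers, with that number as a block, both lists lay higher in the Axin1 libraries (camera adjusted p 0.0129 and 0.0113), each with an adjusted p = 0.808 with an estimated correlation. For neural markers the median was -0.05 and the mean 0.01, with the camera direction up. Their mean log2 CPM was 2.73, 3.59 and 4.63 in controls 1, 2 and 3 and 3.45, 4.09 and 4.17 in the Axin1 libraries. Of the sex-linked genes, Ddx3y and Eif2s3y had 0 reads in control 1, which allows up to 0.256 CPM by counting error. Ddx3y lay at 119 and 40.6 CPM in controls 2 and 3 and at 43.8, 86.2 and 151 CPM in Axin1 libraries 1, 2 and 3. Xist was present in all 6 libraries, at 32.3 to 122 CPM.

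**Figure D3:**
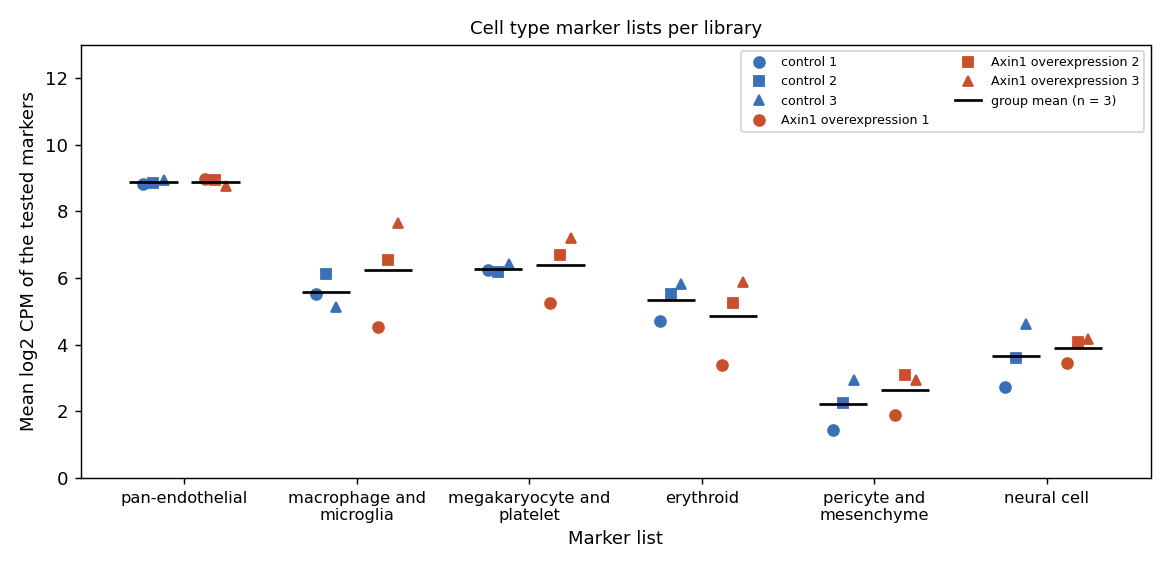
Mean log2 CPM of the measured markers of 6 cell type lists in each library, with a bar at the mean of each group (n = 3). Pan-endothelial markers lie between 8.76 and 8.97 in all libraries, while macrophage and microglia markers range from 4.54 to 7.66 within the Axin1 group.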

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

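The GC and length correction, the list test without called members and the estimated correlation within each alternative were chosen after seeing the data. All of the 107 called genes present under an alternative kept their direction in it. Their groups did not overlap, so fits that left out 1 library could hardly turn them. Calls (higher and lower) numbered 672 (376 and 296) by DESeq2, 197 (94 and 103) with no filter, 400 (210 and 190) by voom with the title number as a random block, 771 (476 and 295) by voom with quality weights, 251 (109 and 142) with 1 surrogate variable and 1500 (969 and 531) in the 4 libraries that share title numbers. With at least 5 CPM in 3 libraries 71 genes were higher, of 147. The 1500 calls come from a fit with almost no residual degrees of freedom. The main test gave 107 (45 and 62). DESeq2 size factors, upper-quartile scaling and the GC and length correction gave 103, 114 and 90 calls, 101, 102 and 81 of them among the 107. Leaving out 1 library gave 0 to 695 calls, 0 to 513 higher and 0 to 182 lower, with 1539 or more genes at an unadjusted p under 0.05 in edgeR. The causes were not tested. Erythroid genes left out of the totals changed none of the 107 calls, since TMM nearly cancels the totals.

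Leaving out 1 library gave log2 fold changes of 1.60 to 1.85 for Axin1 and -1.11 to -0.95 for Adamtsl2, and 3 to 8 lists past the threshold. With all libraries 4 lists passed by camera. With an estimated correlation 0 passed (1 at an unadjusted p under 0.05), and by the directional test of fry 1, the Wnt target list (adjusted p 0.0472). The mixed test of fry asks whether members change in any direction. Many lists passed it, such as VEGF and tip cell genes (adjusted p 7.2e-06) and pan-endothelial markers (0.0243), while others did not, such as proliferation genes (0.151). Neither fry test compares a list with the other genes. Under the other alternatives 0 lists passed with an estimated correlation (lowest adjusted p 0.42), DESeq2 apart, which has no list test. The Wnt and barrier lists without called members had an adjusted p = 0.908 and an adjusted p = 0.745 with an estimated correlation. For Wnt targets the adjusted p was 0.0532 in the 4 libraries, 0.699 with an estimated correlation and 0.464 without called members, which weakens it by construction. It ranged from 4.8e-04 to 0.0355 when 1 library was left out.

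Deviations of same-numbered libraries correlated across genes at 0.23 and 0.15 for replicates 1 and 2, which share title numbers, and at -0.02 for replicate 3, which does not. Control 2 correlated more with Axin1 library 3 (0.175), with which it shares no number. The voom correlation within title numbers was 0.213, and whether these numbers mark a shared litter or sort is not given in the sources used here. With the replicate block 105 genes were called (51 and 54), 59 of them among the 107, and erythroid markers were lower (0.0134, or adjusted p = 0.856 with an estimated correlation). Among named genes the block ended the calls of Pfn1, F2r, Npdc1, Dut, Foxq1, Jag1, Sparc and Igfbp3 (adjusted p in edgeR 0.051 to 0.0822) and the GC and length correction those of F2r, Dut, Foxq1, Sparc and Mcm6 (0.056 to 0.0672). Sparc also ended with DESeq2 size factors (0.0516), Npdc1 and Mcm6 with upper-quartile scaling (0.053 and 0.052), and Pfn1 with no filter (0.0533) and in the 4 libraries (0.15). The causes were not tested.

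The reversed results were not called in the main test, and of them megakaryocyte markers without Axin1 library 1 alone passed in the other direction (1.2e-04, or adjusted p = 0.776 with an estimated correlation). In the 4 libraries Pax6 was at 0.30, F13a1 at -0.0506, Cd68 at -0.0874, Ptprc at -0.15, Epb4.2 at -0.49 and Plek at -0.34. Epb4.2 was at -0.0224 by voom with the random block and -0.29 with the surrogate variable, and Pax6 at 0.16 with quality weights. List directions turned for pan-endothelial (adjusted p 0.663) and macrophage markers (0.207) in the 4 libraries, for arterial genes with no filter (0.981) and the block (0.892), and for megakaryocyte markers with upper-quartile scaling (0.901), the block (0.892) and the GC and length correction (0.999).

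When 1 library was left out, log2 fold changes spanned 0 for Pax6 (-1.46 to 1.04), Hba-x (-1.35 to 0.16), Dcx (-0.12 to 0.75) and Plek (-0.11 to 1.16). List directions turned in at least 1 of these fits for the following lists, with an adjusted p in the turned fits of 0.716 or more except for megakaryocyte markers. Over all 6 fits, turned or not, the preset adjusted p was 0.588 to 0.96 for basement membrane genes, 0.518 to 0.983 for arterial genes, 0.0864 to 0.883 for neural, 0.0417 to 0.96 for pericyte markers, 0.588 to 0.96 for Notch genes, 0.0038 to 0.716 for erythroid, 1.2e-04 to 0.983 for megakaryocyte markers, 0.557 to 0.993 for hypoxia genes, 0.557 to 0.98 for pan-endothelial and 1.6e-07 to 0.783 for macrophage markers. With an estimated correlation 0 of these lists passed in any of the 6 fits.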

Other observations

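Of the tests in this part, the GC and length tests for Cldn5 and the ribosomal protein genes were written before their result was seen, and the others (splits, endothelial share, mislabelling, covariates and correlation between genes) were chosen only after the result was seen.

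Solute carrier genes were singled out after they were seen among the genes that fell. Of 220 tested Slc genes 9 fell (4.09%), against 53 of 12441 other genes (0.426%), and 2 Slc genes rose. Those that fell were Slc2a1, Slc7a5, Slc38a3, Slc19a3, Slc1a4, Slc7a7, Slc12a7, Slc35f2 and Slc39a8, of which Slc1a4 (log2 -1.60) and Slc7a7 (log2 -0.96) carry amino acids, Slc12a7 (log2 -0.67) cotransports potassium and chloride, and Slc39a8 (log2 -0.87) imports zinc. Without the barrier list 6 of 212 Slc genes fell. Without control 2 or without Axin1 library 2 edgeR called 0 genes of any kind, with 1539 and 1733 at an unadjusted p under 0.05.

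Other called genes were singled out after their values were seen. Ptgis, the prostacyclin synthase gene, had the smallest p of all genes and fell by 1.35 on the log2 scale (135 ± 8.19 to 53.1 ± 3.15 CPM, edgeR adjusted p 0.00461, lower in 3 of 3 libraries). The reelin receptor gene Lrp8 fell by 1.71, the secreted Dkk3 by 1.52 and the Wnt-modulating membrane protein gene Tpbg by 1.68. The endothelin receptor gene Ednrb rose (log2 1.52). The edgeR adjusted p values of these 4 genes were 0.0347, 0.0397, 0.038 and 0.0397.

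The real split of the libraries called 107 genes and the highest other split 1, so that 1 of 10 splits gave as many. With 10 splits the share cannot fall under 0.05. For gene lists 7 of the 10 splits put as many lists past the threshold as the real one (4), and the highest other split put 8. That split set control 1 with Axin1 libraries 1 and 2 against the rest, so the list counts follow other differences between libraries too.

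Cldn5 in control 3, whose title number no other library shares, stood 2.08 (log2) above the mean of controls 1 and 2. Correction of each library for its trend with GC content and transcript length left 1.89, which argues against that trend as the whole cause. A larger share of endothelial cells would raise the pan-endothelial markers alike, but their median difference was 0.0781, and the 20 markers ranged from -0.41 to 1.06. A mislabelled Axin1 library is argued against by the Axin1 level, 0.334 times that of the lowest Axin1 library, and by Adamtsl2 at 396 CPM against at most 180 CPM. Of the 45 genes that rose, 33 lay in control 3 on the side of the Axin1 libraries, and of the 62 that fell 27 did. The median position of control 3 on the way from controls 1 and 2 to the Axin1 libraries was 24.1% over all 45. Over all 62 it was -3.61%. A difference between litters or sorts was not tested and stays open.

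Ribosomal protein genes, a set singled out after its values were seen, were lower in sign for 69 of 73 tested genes (median log2 -0.40). By edgeR 4 members fell (Rplp0, Rplp1, Rplp2 and Rps26), whose pseudogenes make their counts uncertain. After the GC and length correction the median was -0.24, past the bound of -0.2 set beforehand for excluding the trend. The mean of the set was -0.19, short of that bound, with a standard error between libraries of 0.07. Before correction the mean was -0.34 (standard error 0.09). The corrected median passed the bound by less than the standard error of the corrected mean. By that bound alone, a length or GC trend would not account for the whole shift. The need to pass the bound by more than the error was added after the value was seen. Under that need the values cannot tell whether the trend accounts for the part of the shift that the correction left.

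The p53 and apoptosis list lay at a mean log2 CPM of 4.76, 4.06 and 4.65 in the controls and 5.22, 5.22 and 5.17 in the Axin1 libraries. With the macrophage list level as a covariate its median log2 fold change was 0.70 against 0.69 without. The difference of the list mean was then 0.76 (standard error between libraries 0.25), an error poorly known from 6 libraries. Macrophage levels were 5.51, 6.13 and 5.14 in controls 1, 2 and 3 and 4.54, 6.54 and 7.66 in Axin1 libraries 1, 2 and 3. The p53 list did not rise with them within either group, which argues against macrophages as the whole cause. With the dissociation stress level as a covariate the median was 0.65. The difference of the list mean was 0.67 (standard error 0.37), too wide an error to exclude that stress of dissociation may contribute. Correlation between the genes of the list is consistent with the data as an explanation of the list's small preset p, since the unadjusted p with an estimated correlation was 0.125. Axin1 overexpression itself stays open as a biological explanation.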
